A study of Drosophila melanogaster with 24 samples.

How the data were processed

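RNA from imaginal discs of wandering third-instar larvae was hybridised to oligonucleotide arrays of 2 designs, lm and lmC, with 12 arrays each. Per the labels, eye targets came from 100 discs of the strain iso4 and 1 to 2 µg of total RNA through 2 rounds of cDNA synthesis. Control leg (iso4) and leg_ey (dppblink-GAL4 driving UAS-ey) targets came from 100 to 200 discs per dissection and 500 to 700 per target, with 15 to 20 µg of RNA and a standard procedure. Groups and array numbers follow the sample titles: eye 17, 18, 29, 30 and 31 on lm and eye 17, 30, 31, 44 and 45 on lmC, with leg 49 to 51 and leg_ey 52 to 55 on both. Nothing says whether targets of a group came from separate larvae or crosses, so p-values measure only the spread between these arrays, which may be technical. Arrays with the same number on both designs may carry the same RNA, and the designs were never counted as independent replicates.

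The deposited values are probe set intensity on a linear scale, 1 value per probe set. The values hold 1 decimal, many lie below 0 and array medians differ several-fold, so no scaling between arrays is visible. The software that made them is not given in the sources used here. No pair of columns was identical among 66 pairs per design, with Spearman correlations from 0.551 to 0.955 on lm and from 0.625 to 0.953 on lmC. On lm arrays 32.2% to 39.1% of values were below 0 in eye, 22.6% to 28.9% in leg and 21.8% to 23.8% in leg_ey discs.

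Each design was quantile normalized between its 12 arrays. Values were raised to a floor, the 25th percentile of the normalized values but at least 1, and log2 transformed. The floor was 1 on lm, where the 25th percentile was negative, and 1.24 on lmC. Probe sets above the floor on at least 3 arrays were tested and control probe sets left out (32 on lm and 44 on lmC). The limma functions lmFit and eBayes with a trend were fitted to 3 group means over all 12 arrays, and p-values were Benjamini-Hochberg adjusted, with 0.05 as the threshold. A floor of 1 stretches log2 differences of dim genes. Where all arrays of a group lay at or below the series median (170.5 on lm, 99.4 on lmC), differences are therefore given as "at least N-fold", the ratio of group means on the log2 scale with the floor at the 50th percentile. Adjusted p-values beside such folds come from the fit with the floor of 1, unless the floor at the series median is named. These folds are bounds only for values raised to the floor and do not allow for sampling error.

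Probe set IDs on lm hold gene names or locus tags. Of 14038 probe sets, 13017 matched 1 gene of the RefSeq gene table (assembly Release 6, used for names alone): 10555 by locus tag, 1625 by symbol and 837 by synonym. Another 460 matched several genes, 71 were ambiguous in upper and lower case and 490 had no match. These name 11272 genes, 1261 of them with more than 1 probe set, and a gene is represented by its probe set with the highest mean. The IDs on lmC are numbers, no table used here pairs them with genes, and their genes are not named here. Results joining both designs by gene were planned and are not given for this reason.

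Named genes were chosen by a rule. For each comparison it takes ey and all measured retinal determination genes. It adds the 6 called genes with the largest absolute log2 difference in each direction that lay above the floor in more than 50% of the arrays of both groups, and the 3 called genes with the highest mean in each direction that lay at the floor on all arrays of the other group. From each further list it takes the 3 called members with the largest absolute log2 difference, or the 2 with the highest mean if none was called. The choice used lm alone, since lmC genes are not named. The 21 lists were retinal determination, furrow and R8, photoreceptor specification, Notch and E(spl) targets, neuronal differentiation, phototransduction, eye pigment, leg proximodistal patterning, Hox and segment identity, signalling and patterning, cell cycle and replication, glia, muscle and mesoderm, hemocyte, fat body and salivary gland, trachea, heat shock and stress, JNK signalling and cell death, ecdysone response, oxidative phosphorylation and ribosomal proteins. They were tested by camera with a preset correlation of 0.01 and with an estimated one. Groups, tests, the rule for named genes, the lists and the first set of other settings were fixed before the data were examined. The bound given as "at least N-fold", the lowest intensity used in control ratios and the settings called added were chosen later.

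Settings tried besides were 75th percentile scaling, values as deposited, floors at the 10th and 50th percentiles, no filter, no trend, array weights, fits of only the groups compared, a 2-fold threshold, each array left out, the mean over the log2 values of the tested probe sets of a gene (lm) and the estimated correlation. Added after the data had been seen were fits without eye 17 and eye 18, fits without leg 49 or of only both leg groups with the floor at the 50th percentile, lists under each scaling, with that floor and without each array, the retinal determination list without ey, and fits of the eye and leg_ey arrays normalized without the leg arrays. Pairs of glue and fat body genes were tested by exact two-sided permutation of arrays within each group. Control transcripts were compared on lmC by exact two-sided permutation tests of the log2 ratio of 3' to 5' probe sets, with intensities raised to at least the series median.

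The fits were tested on simulated data in which 200 probe sets were changed 2-, 4-, 8- or 16-fold, 50 each. The changed probe sets were drawn from those above the median level. The first version drew each probe set with its own spread per group. In it 45.8%, 37.8% and 33.0% of calls were false on lm (eye against leg, leg_ey against leg, eye against leg_ey) and 38.0%, 26.5% and 23.7% on lmC, far above the 5% aimed at, with 71, 61 and 65 of the 200 recovered on lm and 101, 83 and 100 on lmC. A second version, added after that result was seen, drew the spread as a smooth function of the mean. It gave 11.1%, 2.53% and 6.90% false calls on lm and 2.52%, 0% and 4.72% on lmC, with 80, 77 and 81 recovered on lm and 116, 127 and 121 on lmC. For leg_ey against leg on lm it recovered 3, 22, 24 and 28 of 50 at the rising fold sizes, among 11940 probe sets tested. How closely arrays of a group followed each other differed between groups. Median Spearman correlations of an array with its own group were 0.735 to 0.784 in eye, 0.766 to 0.854 in leg and 0.941 to 0.953 in leg_ey discs on lm, and 0.793 to 0.823, 0.826 to 0.878 and 0.939 to 0.951 on lmC. On lm leg 50 and leg 51 followed the leg_ey arrays (medians 0.932 and 0.905) more closely than their own group (0.818 and 0.854), unlike leg 49 (0.731 and 0.766). The same held on lmC (0.918 and 0.913 against 0.846 and 0.878, with 0.811 and 0.826 for leg 49). Estimated array weights on lm were 0.291 to 0.618, 0.247 to 2.77 and 2.62 to 4.84. The share of false calls may therefore lie well above the threshold. In a simulated test of 20 lists over 2000 genes, the 1 shifted list was found and none of the others. Its values were drawn independently for each gene, so it cannot tell how the list test fares with correlated genes. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.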

Results

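Gene expression was measured in imaginal discs of wandering third-instar Drosophila larvae, the epithelial sacs that form the adult eye and leg. Eye discs and leg discs of a control strain (iso4) were compared with leg discs in which the driver dppblink-GAL4 turned on a UAS-ey transgene. The gene ey (eyeless) encodes a Pax6 transcription factor that can start eye development, and the design asks which eye genes it turns on in leg tissue. Targets were hybridised to oligonucleotide arrays of 2 designs, called lm and lmC here, with 12 arrays per design and some eye array numbers on 1 design alone. These were 5 of eye discs, 3 of control leg discs and 4 of leg discs with ectopic ey, written leg_ey. Arrays are named by group and number, such as leg 49. Genes could be named on the lm design, and lmC probe sets are given as counts and levels. The median deposited intensity on lm arrays was 40.05 to 78.05 in eye discs, 102.45 to 274.9 in control leg discs and 195.95 to 342.7 in leg_ey discs. Eye targets came from 1 to 2 µg of RNA through 2 rounds of cDNA synthesis and leg targets from 15 to 20 µg by a standard procedure. Tissue and target preparation therefore cannot be told apart in any comparison with eye discs. Values below are mean normalized intensity ± SD over n = 5 eye, n = 3 leg and n = 4 leg_ey arrays, and log2 differences carry ± SE. All adjusted p-values come from limma, and the number of arrays limits the precision.

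The first comparison set leg_ey discs against control leg discs. No arrays held the driver or the transgene alone, so an effect of ey cannot be told apart from one of genotype. The ey transcript itself was 3306 ± 554 in leg_ey discs against 134 ± 103 in control leg discs, a log2 difference of 4.88 ± 0.41 (adjusted p = 0.000194). All 4 leg_ey arrays lay above all 3 leg arrays. In eye discs, where ey is normally active, it was 2659 ± 375. The next gene of the retinal network, eya, which encodes a phosphatase and transcriptional partner, was 1648 ± 172 in leg_ey discs and 22.2 ± 200.1 in leg discs. Arrays again did not overlap, but adjusted p was 0.208. With the floor raised to the series median it passed, at least 9.63-fold higher with adjusted p = 0.0167. Over the settings planned its adjusted p ran from 0.00726 to 0.477, the highest without leg_ey 55. The partner of eya, so, was 359 ± 173 against -10.7 ± 288 (adjusted p = 0.841), and dac, which both legs and eyes express, was 2683 ± 204 against 1566 ± 1111 (0.795). The second Pax6 gene toy and the homeobox gene Optix stayed at background in leg_ey discs, at -69.4 ± 65.1 and -32.1 ± 147, with adjusted p = 0.818 and 0.933. The other members eyg, toe, dan, danr, tsh, hth and nmo did not pass either. Of these danr was at 605 ± 66.1 against 329 ± 109.5 (0.838) and tsh at 857 ± 128 against 521 ± 496 (0.826). The leg mean of tsh was lowered by leg 49, at -49.7 against 851.3 on leg 50 and 761.8 on leg 51. For dac these arrays gave 369.8, 2564.6 and 1763.1, while danr was highest on leg 49 among the leg arrays.

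**Figure D1:**
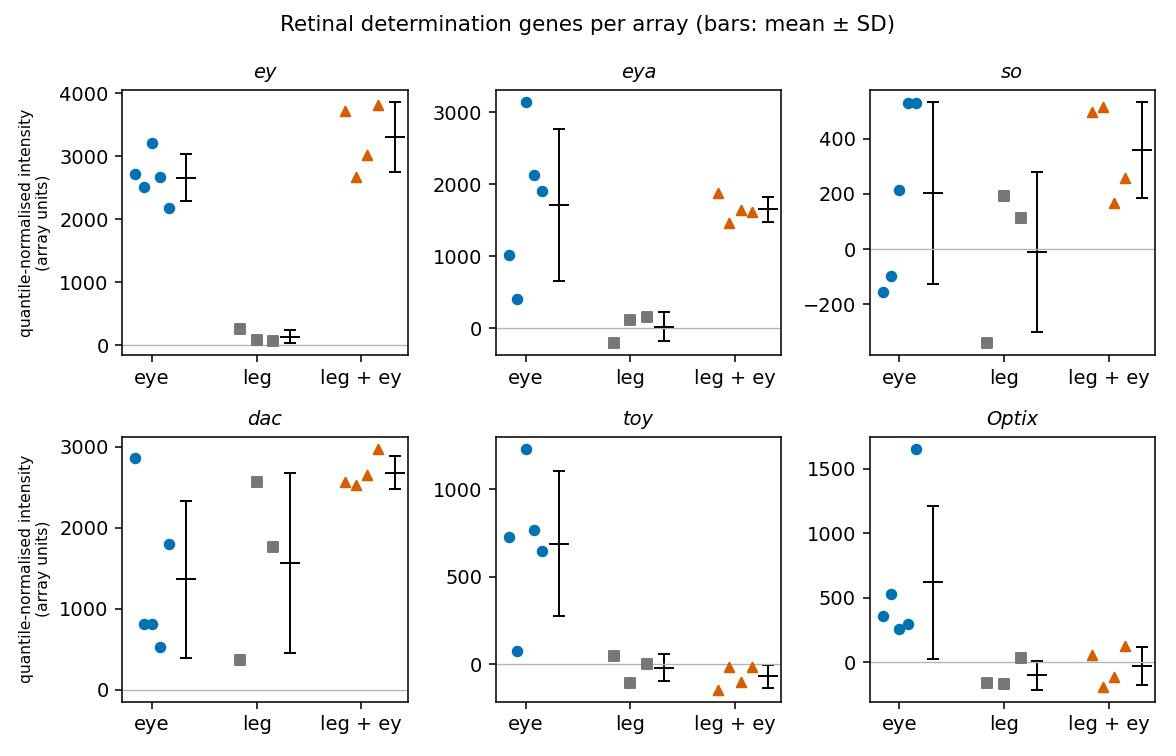
Normalized intensity of ey, eya, so, dac, toy and Optix on each lm array of eye, leg and leg_ey discs; points are arrays and bars are the mean ± SD over 5, 3 and 4 arrays. The 4 leg_ey arrays lay above all 3 leg arrays for ey and eya, and all 5 eye arrays lay above every other array for toy and Optix.

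Few other genes separated leg_ey from control leg discs. Ilp8, a relaxin-like peptide released by damaged or slow-growing discs, was 1639 ± 228 against 28.1 ± 60.8, at least 9.54-fold higher (adjusted p = 0.0438). The Ly6-family gene twit rose at least 3.96-fold (696 ± 194 against 12.4 ± 42.5, adjusted p = 0.0318) and Tektin-C at least 2.24-fold (382 ± 30.7 against -95.7 ± 48.9, 0.0438). Prosalpha1, a subunit of the proteasome core, fell from 14088 ± 2046 to 6443 ± 316, a log2 difference of -1.12 ± 0.20 (0.0438), and its other probe set gave -1.13. The salivary glue gene Sgs7 was at least 50.8-fold lower in leg_ey discs (-390.3 ± 428 against 10758 ± 8616, 0.00693) and the yolk protein gene Yp1 was higher (244 ± 186 against -94.2 ± 49.6, 0.00798). Yp1 was below the series median of 170.5 on leg_ey 52 and leg_ey 53 and was not tested with the floor there. Calls of mtt, Ank2 and CG11382 upward and of Osi19 and CG14154 downward rested on values near background. The gene mtt was 247 ± 99.9 against -143 ± 87.3 and Osi19 -313 ± 197 against 458 ± 256 (both adjusted p = 0.000194). With the floor at the series median their adjusted p was 0.725 and 0.472. For Ank2 and CG11382 it was then 0.972 and 0.92, and CG14154 was no longer tested. Sgs3 was -34.6 ± 36.8 against 2177 ± 2422, well above background in leg discs, and with that floor its log2 difference was still -3.05 though adjusted p was 0.37. Its call was also lost with 75th percentile scaling (0.0643) and on values as deposited (0.0977), as were those of CG14154, Prosalpha1, Ank2 and CG11382 (up to 0.515, 0.576, 0.104 and 0.625). Ilp8 lost its call with 75th percentile scaling (0.0516), without the filter (0.101) or the trend (0.063) and with only both leg groups in the fit (0.26), where twit, Ank2 and Sgs7 lost theirs too (0.252, 0.134 and 0.0954). The calls of Prosalpha1 and twit were lost without the filter (0.0535 and 0.0538) and that of Prosalpha1 without the trend (0.491). With the mean over the probe sets of a gene, mtt and Ank2 lost theirs (0.816 and 0.928). Leaving out 1 array ended several calls. Ilp8 lost its call without any 1 eye or leg_ey array (adjusted p up to 0.127, without leg_ey 55). The call of twit was lost without any 1 array but leg 50 or leg 51 (up to 0.0971), that of Tektin-C without any 1 but eye 17 or leg 50 (up to 0.149) and that of Prosalpha1 without any 1 but eye 18, eye 29 or leg 50 (up to 0.191). Ank2 lost its call without eye 17, eye 18 or leg_ey 54 (up to 0.058), CG11382 without leg 51 or any leg_ey array (up to 0.117) and CG14154 without eye 17, eye 18, leg 51 or any leg_ey array (up to 0.123). The calls of ey, mtt, Osi19, Sgs3, Sgs7 and Yp1 passed in all 12 such fits.

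In all, 22 lm probe sets of 12292 tested rose and 10 fell in leg_ey discs, covering 18 and 7 genes of 10056, and 758 probe sets had an unadjusted p under 0.05. On lmC arrays 26 rose and 20 fell of 12597, with 924 at an unadjusted p under 0.05. Chance alone puts about 5% of tested probe sets there. Without leg 49 they were 456 of 12146 on lm and 592 of 12442 on lmC, both below that share. In the simulations with each probe set's own spread, 37 unchanged probe sets were called on lm and 30 on lmC. With the smooth spread they were 2 and 0, so how many of the 32 and 46 calls are false stays open. Of the 3 lmC probe sets with the smallest adjusted p (2.49e-05), 1 rose from 111 ± 48.5 in leg discs to 3782 ± 226 in leg_ey discs. The others fell from 2848 ± 61.4 to 74.3 ± 28.7 and from 6334 ± 5429 to -232 ± 163. These counts depended on single arrays. The lm total of 32 became 139 without leg 50, 21 without leg_ey 54 and 18 without leg_ey 55. The lmC total of 46 became 91 without leg 50, 27 without leg_ey 53 and 29 without leg_ey 55. With estimated array weights the totals were 398 and 960, with only both leg groups in the fit 79 and 161, and the 75th percentile scaling gave 20 on lm.

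Among 21 gene lists, 12 stood above other genes in leg_ey discs and 1 below, by camera with a preset correlation. With an estimated correlation none passed, so the rises and the fall below hold with the preset one alone. The retinal determination list rose (1 of 13 members, ey, passed over all genes and 2, ey and eya, adjusted over the list alone; adjusted p = 0.000104). As ey was driven by design, the list was also tested without it, and its other 12 members rose as a list (0.00543, and adjusted p = 0.169 with an estimated correlation) but not without leg 49 (0.075). Neuronal differentiation (1 of 19, Ank2, and 2 adjusted over the list alone; 0.000153, and 0.0769 with an estimated correlation) rose too. So did photoreceptor specification (0 of 19 and 1; 0.00091, and 0.0954). JNK signalling and cell death (1 of 14, Ilp8, and 2; 0.00277, and 0.0769) and Notch and E(spl) targets (0 of 12 and 1; 0.0397, and 0.169) also rose. No member passed either way in the other 7 risen lists, which were leg proximodistal patterning (22 members, 0.00234), signalling and patterning (17, 0.00574), trachea (8, 0.00574), furrow and R8 (12, 0.00808), glia (10, 0.00904), hemocyte (13, 0.0247) and muscle and mesoderm (18, 0.0397). Fat body and salivary gland genes fell as a list (2 of 16 lower, Sgs3 and Sgs7, and 1 higher, Yp1; 5 lower and 1 higher adjusted over the list alone; 1.08e-05). With an estimated correlation the risen lists had adjusted p = 0.0769 to 0.219 and fat body and salivary gland 0.148. The 8 lists that did not pass were Hox and segment identity (0.194), oxidative phosphorylation (0.195), cell cycle and replication (0.428), ribosomal proteins (0.428), eye pigment (0.71), phototransduction (0.817), heat shock and stress (0.817, 0 of 10 over all genes and 1 lower adjusted over the list alone) and ecdysone response (0.907). Cell cycle had a median log2 difference of -0.02 and a mean of 0.24, and ecdysone response -0.18 and 0.41, while both tests pointed up. The lmC array leg 49 had 3'-biased control transcripts, at a log2 ratio of at least 7.0 for actin against 0.77 on leg 50, while lm holds no such transcripts and its leg 49 may or may not carry the same target. Without leg 49 on lm 5 of the 12 lists stayed up, namely retinal determination (0.000335), neuronal differentiation (0.00011), photoreceptor specification (0.00648), JNK signalling (0.0104, median -0.02) and Notch targets (0.0202, median -0.04). Fat body and salivary gland stayed down (1.11e-05). With an estimated correlation none of these 5 lists passed without leg 49 (adjusted p = 0.126 to 0.213), nor did fat body and salivary gland (0.213). The Notch target list lost its call without eye 18, leg 50, leg 51, leg_ey 53 or leg_ey 54 (up to 0.159) and with 75th percentile scaling (0.347). The muscle list lost its call without eye 18, leg 51 or leg_ey 52 as well and the hemocyte list without leg 51. With the floor at the series median 9 lists stayed up, while leg proximodistal patterning, signalling and patterning and glia missed the threshold (adjusted p = 0.0587, 0.119 and 0.109).

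**Figure D2:**
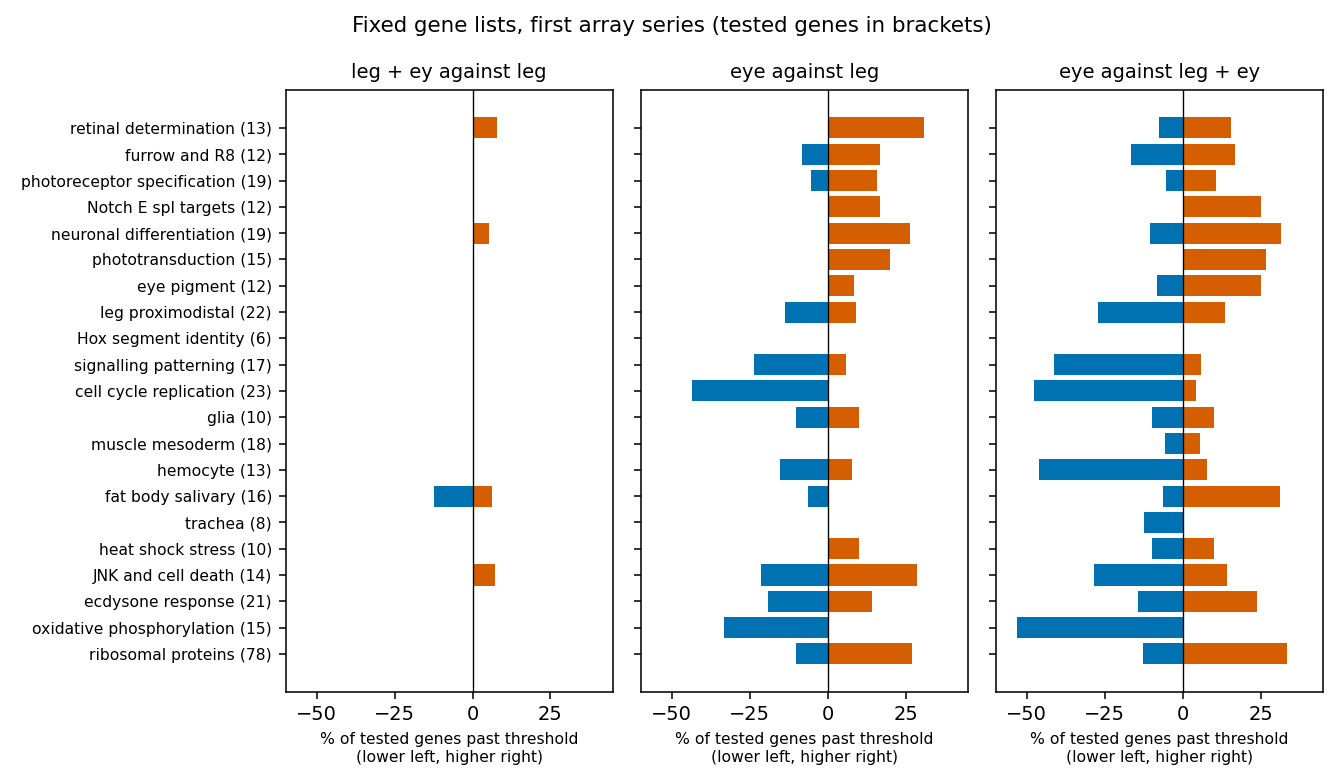
Percent of the tested members of each gene list that passed adjusted p 0.05 on lm arrays, higher to the right and lower to the left, for the 3 comparisons. Some cell cycle and oxidative phosphorylation genes were lower in eye discs than in either leg group, with 10 of 23 and 5 of 15 members lower against control leg discs. With 75th percentile scaling the oxidative phosphorylation list, still lower, missed the threshold. With an estimated correlation both lists missed it, with adjusted p = 0.145 against leg and 0.138 against leg_ey discs.

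The fat body and salivary gland list holds markers of tissues outside the disc. Glue proteins are made by the salivary gland, and the fat body makes the storage protein of Lsp2 and the storage protein receptor of Fbp1. Sgs7 ranged from 4175 to 20510 on leg arrays, from 1401 to 23056 on eye arrays and from -815 to 91.2 on leg_ey arrays. Sgs4 ranged from 1012 to 4391, 260.1 to 11969.9 and -106 to 105. Lsp2 was 14136 ± 8476 in leg, 2969.6 ± 3026 in eye and 4032 ± 585 in leg_ey discs, and Fbp1 6185 ± 2958, 327 ± 776 and 1186 ± 602.

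**Figure D3:**
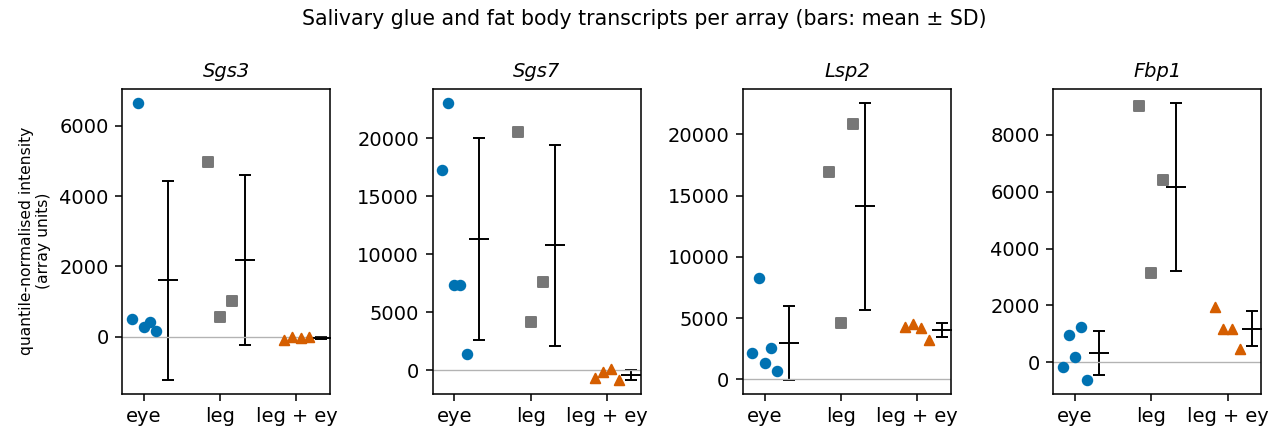
Normalized intensity of the glue genes Sgs3 and Sgs7 and of the fat body genes Lsp2 and Fbp1 on each lm array of eye, leg and leg_ey discs; points are arrays and bars the mean ± SD over 5, 3 and 4 arrays. Sgs7 lay between -815 and 91.2 on the leg_ey arrays and at 1401 or above on all other arrays.

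The second comparison asked how eye discs differ from leg discs. In eye discs ey was higher by 4.57 ± 0.39 on the log2 scale (adjusted p = 4.53e-05), eya at least 8.14-fold (1716 ± 1055 against 22.2 ± 200.1, 0.0146) and toy at least 3.50-fold (691 ± 412 against -19.7 ± 78.0, 0.00848). Of 12 Notch and E(spl) target genes 2 were higher, and the list did not pass. E(spl)mgamma-HLH was 13881 ± 2594 against 819 ± 416 (log2 4.19 ± 0.30, 1.42e-05), E(spl)m4-BFM rose by 2.16 ± 0.21 (7.75e-05) and aos, a secreted Egfr inhibitor, by 4.26 ± 0.69 (0.00181). The rhomboid protease gene ru (2.33 ± 0.32, 0.000649) and the photoreceptor diacylglycerol kinase gene rdgA (2.38 ± 0.27, 0.000186) rose likewise. Of the leg patterning list, which did not pass as a whole, 2 members were higher and 3 lower in eye discs. The gene al, which marks the distal leg, was -959.8 ± 344 against 1441 ± 172, at least 8.42-fold lower (4.53e-05), btd at least 2.93-fold (8.29e-05) and inv, a posterior compartment gene, at least 2.38-fold (0.0057). These calls passed in all 12 fits that left out 1 array. The call of toy was lost with 75th percentile scaling (adjusted p = 0.0865) and on values as deposited (0.142), and that of eya with only eye and leg arrays in the fit (0.0628).

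The genes mtt, nrv3, Ank2 and twit, of which nrv3 and Ank2 belong to the neuronal differentiation list, were at background in leg discs and higher in eye discs. The metabotropic glutamate receptor-related gene mtt was at least 10.9-fold higher (1877 ± 245 against -143 ± 87.3, adjusted p = 2.9e-06), the sodium pump subunit gene nrv3 at least 4.97-fold (0.000166), the ankyrin gene Ank2 at least 2.49-fold (0.000275) and twit at least 5.30-fold (0.00111). Ilp8 was at least 2.93-fold higher (0.0124), the small heat shock gene Hsp67Bc was 2947 ± 427 against 20.9 ± 227 (0.0051) and the cuticle protein gene Ccp84Ag 6632 ± 3370.2 against 114 ± 829 (0.00887). CG31676, CG10953 and CG14459, at background in leg discs, were at least 14.8-, 11.5- and 9.12-fold higher. Among genes lower in eye discs, the serine hydroxymethyltransferase gene Shmt was at least 10.6-fold lower (1.01e-05), the ESCRT-III gene Vps2 at least 8.11-fold (1.42e-05), the exocyst gene Sec5 at least 4.85-fold (0.00476), and Pebp1, GstT4 and CG5969 at least 6.02-, 3.77- and 7.34-fold. CG1572 was 21.7 ± 114 against 2522 ± 435 (0.00503). With only eye and leg arrays in the fit Pebp1, GstT4, CG5969 and Ilp8 lost their calls (adjusted p = 0.0581, 0.0532, 0.0532 and 0.0706), as did Ccp84Ag with array weights (0.0572).

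Some genes of DNA replication and of the respiratory chain were lower in eye discs, and both lists fell with the preset correlation alone. The replication clamp gene PCNA was 421 ± 253 against 3673 ± 1344, a log2 difference of -3.36 ± 0.54 (adjusted p = 0.00179). Of 23 cell cycle and replication genes, 10 fell with none rising (10 adjusted over the list alone; list adjusted p = 0.000713, and 0.145 with an estimated correlation). COX5A (-1.22 ± 0.20), COX5B (-1.43 ± 0.26) and ND-42 (-1.54 ± 0.29) led 5 of 15 oxidative phosphorylation genes that fell (7 lower and 1 higher adjusted over the list alone; 0.0065, and 0.145). That list did not pass with 75th percentile scaling (adjusted p = 0.1). On lmC eye targets had 3'-biased control transcripts, at a log2 ratio of at least 6.17 ± 0.88 for actin. Retinal determination genes rose as a list, with 4 of 13 passing (4 adjusted over the list alone; 0.0205, and 0.281 with an estimated correlation), though on values as deposited their median was -0.42 with the test still up. Neuronal differentiation rose too, with 5 of 19 (8 adjusted over the list alone; 0.00493, and 0.171). Without leg 49 both rises missed the threshold (adjusted p = 0.117 and 0.0855), the 2 falls remained (0.00132 and 0.00325) and signalling and patterning genes fell (0.017). With an estimated correlation these 3 falls then had adjusted p = 0.274. Without eye 29 the rise of retinal determination missed it too (0.0514). The other 17 lists had adjusted p = 0.0769 to 0.937, and the counts in them were the same adjusted over the list alone unless given. Ribosomal protein genes went both ways (21 higher and 8 lower of 78, 23 and 9 adjusted over the list alone; 0.13), with RpS5a, RpS25 and RpS27 higher by 2.34 ± 0.49, 1.76 ± 0.29 and 1.27 ± 0.19 (RpS5a not past the threshold with array weights, 0.065). Passing members numbered 3 of 15 for phototransduction (0.0769), 2 of 12 for Notch targets (0.13), 3 higher and 1 lower of 19 for photoreceptor specification (0.164), 1 and 4 of 17 for signalling and patterning (0.164). They were 2 and 3 of 22 for leg patterning (3 and 3 adjusted over the list alone; 0.797), 4 and 3 of 14 for JNK signalling (0.797). There were 3 and 4 of 21 for ecdysone response (4 and 4; 0.797), 1 and 2 of 13 for hemocyte (0.601) and 0 and 1 of 16 for fat body and salivary gland (0 and 4; 0.164). They numbered 2 and 1 of 12 for furrow and R8 (0.814), 1 and 0 of 12 for eye pigment (0 adjusted over the list alone; 0.797), 1 and 1 of 10 for glia (0.797) and 1 and 0 of 10 for heat shock (0.61). None passed for Hox (0.937), muscle (0.797) and trachea (0.572). Furrow and R8, JNK signalling and ecdysone response had a negative mean (-0.77, -0.49 and -0.70) with a test pointing up. Ecdysone response and hemocyte had a positive median (0.58 and 0.27) with a negative mean. Hox had a median of 0.04 and a mean of -0.24, and heat shock a median of -0.61 and a mean of 0.10. With the floor at the series median phototransduction and photoreceptor specification rose as lists (adjusted p = 0.0139 and 0.0202, and 0.182 and 0.289 with an estimated correlation).

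Other genes of these lists passed with all arrays and lost the call when 1 was left out. Without leg 51 the adjusted p of brp, an active zone protein of synapses (2117 ± 855 against -15.2 ± 186, 0.0109), rose to 0.0575, and those of esg, lz and rdgC to 0.0501, 0.128 and 0.0624. Optix (619 ± 589 against -99.8 ± 113, 0.0231) and rdgB lost theirs without leg 49 or leg 50 (up to 0.0776 and 0.0672). ImpL1 lost it without leg 49 (0.0551), CG11155 without eye 18 or leg 51 (up to 0.0542), and hh, loco and ImpE1 without leg 50 or leg 51 (up to 0.0651, 0.0584 and 0.0947). AlaRS lost it without any 1 leg array (up to 0.0733) and the larval storage protein gene Lsp2, 2969.6 ± 3026 against 14136 ± 8476, without eye 29, leg 49 or leg 51 (up to 0.124). The calls of chp, CycE, Gli, mid, usp, Drice, rpr, LanB2, Col4a1, v and dpa were lost in at least 6 of the 12 fits and that of boss in all 5 in which it was tested. Without leg 51, Col4a1 reached 0.244, CycE 0.192 and Gli 0.19. With the mean over the probe sets of a gene brp, rdgB, rdgC, CycE, loco and ImpE1 lost their calls (adjusted p = 0.235, 0.0603, 0.162, 0.0639, 0.122 and 0.107). Among uncalled genes, Act57B was 7234 ± 1480.3 against 11755 ± 9582 (0.849), but without leg 49 its log2 difference was -1.29 with adjusted p = 0.00134, and tsh and exd then passed too (0.025 and 0.00366, exd with a log2 difference of -2.27). The gene danr (0.145) passed without eye 17 (0.0192). The genes dac (0.942), so (0.935) and hth (0.121) did not pass in any of these fits. With only eye and leg arrays in the fit hh, esg, lz, AlaRS, Lsp2 and rdgB lost their calls (adjusted p = 0.0814, 0.0667, 0.0883, 0.0933, 0.0931 and 0.0653), and Optix did on values as deposited (0.0569) and with array weights (0.241).

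By count, 1096 lm probe sets were higher and 871 lower in eye than in leg discs (882 and 752 genes), and on lmC 1334 were higher and 1305 lower. The lm total of 1967 became 1292 without leg 50 and 929 without leg 51, and the lmC total of 2639 became 1580 without leg 51. On values as deposited the eye arrays lay lower as a whole, with a median log2 difference of -1.87 on lm. The totals were then 4420 and 4549, and 10 of 30 named calls upward were lost (such as ru, adjusted p = 0.217, and rdgA, 0.247) against 1 of 30 downward. Scaling to the 75th percentile moved the share of calls higher in eye discs from 55.7% to 44.5% on lm and from 50.5% to 55.7% on lmC.

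The third comparison set eye discs against leg discs with ectopic ey. After quantile normalization both expressed ey and eya at levels that did not separate (-0.31 ± 0.36 and -0.24 ± 1.23 on the log2 scale, adjusted p = 0.518 and 0.891). On values as deposited the eye arrays lay lower as a whole. There ey was 576.3 to 1397.7 on eye and 3225.1 to 6752.4 on leg_ey arrays, with no overlap. For eya the ranges were 232.1 to 915.7 and 1775.4 to 3441.1, so whether the levels match depends on the scaling. The gene toy was higher in eye discs (691 ± 412 against -69.4 ± 65.1, at least 3.50-fold, 0.000567). E(spl)mgamma-HLH was higher by 2.97 ± 0.27 (3.64e-05), E(spl)m4-BFM by 1.75 ± 0.19 (0.000112), aos by 3.50 ± 0.64 (0.00216), ru by 1.72 ± 0.30 (0.00157) and the light-response phosphatase gene rdgC by 2.30 ± 0.31 (0.000343). The distal leg gene Dll was at background in eye discs and high in leg_ey discs (-74.7 ± 139 against 4137 ± 1094, at least 23.6-fold lower, 0.00585). Lower too were btd at least 6.72-fold (2.33e-05), esg at least 4.57-fold (0.00165) and hh at -49.9 ± 248 against 655 ± 85.0 (0.00477). These calls passed in all 12 fits that left out 1 array. On values as deposited, however, ru turned to -0.39 (adjusted p = 0.35), and E(spl)m4-BFM, aos and rdgC lost their calls.

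Further genes higher in eye discs were phtm, a cytochrome P450 of ecdysone synthesis (3613 ± 455 against -409 ± 236, at least 21.1-fold, adjusted p = 0.000248). Others were Osi19 (at least 16-fold, 3.49e-06), CG31676 (at least 14.8-fold), brp (at least 11.4-fold, 0.0186), pros (2.93 ± 0.77, 0.0145) and the ecdysone-induced gene ImpE3 (2.42 ± 0.30, 0.000214). The glue genes Sgs7, Sgs4 and Sgs3 were higher too, Sgs7 at least 46.1-fold (0.000139) and Sgs4 at least 16.2-fold (0.00198), but eye 18 alone held 6660.3 of Sgs3, which with the median floor had adjusted p = 0.12. Schip1, CG6462, CG12491 and Lcp65Ag2 rose (0.00238, 0.00973, 0.00858 and 0.0179). Genes lower in eye discs included the basement membrane collagen gene Col4a1 (at least 7.17-fold, 0.00182), the chitin deacetylase gene serp (-2.04 ± 0.44, 0.00548), CycE (at least 3.81-fold, 0.00155), the metalloprotease gene Mmp1 (at least 2.05-fold, 0.00162). The T-box gene mid was lower too (at least 3.33-fold, 0.00203), as were usp, path, CG1607 and CG8468 (at least 3.45-, 11.1-, 26.3- and 14.0-fold). The gene dac did not pass (0.117) but did without leg 49 (0.0484), and exd (0.0668) did without leg 49 or leg 50 (down to 0.000289). Both passed on values as deposited (dac 0.00287, exd 0.00788) and with array weights (0.0186 and 0.00799), and exd also with the median floor (0.00425) and with only eye and leg_ey arrays in the fit (6e-04). With the mean over the probe sets of a gene brp, Sh, loco and ImpE1 lost their calls (0.143, 0.0942, 0.672 and 0.061). On values as deposited pros, ImpE3, brp, CG6462, CG12491 and Lcp65Ag2 lost theirs (0.658, 0.595, 0.0641, 0.0731, 0.112 and 0.0755), and with array weights brp, CG12491 and Lcp65Ag2 (0.0582, 0.0506 and 0.0824). Hsp83 was lower by quantile normalization (log2 -0.97 ± 0.26, 0.0158) and 0.026 higher with 75th percentile scaling. Calls that 1 left-out array ended were those of Optix (eye 31, leg_ey 53 or leg_ey 54; adjusted p up to 0.0772), tsh (any eye array but eye 29, or any leg_ey array; up to 0.0791), loco (leg_ey 52; 0.0512), Cyt-c-p (leg_ey 52 or leg_ey 54; up to 0.0533). So were those of bi and Syt1 (leg_ey 52, leg_ey 53 or leg_ey 55; up to 0.0534 and 0.0581), trpl (eye 17, eye 18 or eye 29; up to 0.0769), sens (leg 51, leg_ey 52, leg_ey 54 or leg_ey 55; up to 0.143). In 5 to 7 fits each the calls were lost of Sh, trp, Ras85D, SPARC, Pxn and Lac (up to 0.0905, Lac without eye 18).

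Some replication and respiratory genes were again lower in eye discs, and both lists fell with the preset correlation alone. PCNA was 421 ± 253 against 2765 ± 117 (-3.01 ± 0.50, adjusted p = 0.00128). Of 23 cell cycle genes, 11 fell while CycD rose (12 lower adjusted over the list alone; list adjusted p = 0.000584, and 0.138 with an estimated correlation). Oxidative phosphorylation had 8 of 15 lower (8 lower and 1 higher adjusted over the list alone; 0.00204, and 0.138), including SdhB (-1.62 ± 0.40) and Ucp4A (at least 3.02-fold). With 75th percentile scaling the list did not pass (adjusted p = 0.208). On lmC control transcripts were 3'-biased in eye targets alone here, with actin at no less than 6.17 ± 0.88 against 0.85 ± 0.14. Signalling and patterning genes fell as a list (7 lower and 1 higher, ci, of 17; 8 lower adjusted over the list alone; 0.0149, and 0.311 with an estimated correlation), but on values as deposited adjusted p was 0.11. The other 18 lists had adjusted p = 0.0758 to 0.838. Retinal determination had 2 higher and 1 lower of 13 (0.838), neuronal differentiation 6 and 2 of 19 (0.367), phototransduction 4 of 15 (0.0768), Notch targets 3 of 12 (0.49). Leg patterning had 3 and 6 of 22 (0.0945), hemocyte 1 and 6 of 13 (2 and 6 adjusted over the list alone; 0.193), fat body and salivary gland 5 and 1 of 16 (0.558) and ribosomal proteins 26 and 10 of 78 (0.0768). Furrow and R8 had 2 and 2 of 12 (0.502), photoreceptor specification 2 and 1 of 19 (2 and 0 adjusted over the list alone; 0.838), eye pigment 3 and 1 of 12 (0.602). JNK signalling had 2 and 4 of 14 (3 and 5; 0.367), ecdysone response 5 and 3 of 21 (7 and 4; 0.838), trachea 0 and 1 of 8 (0.0758), glia (0.558), muscle (0.588) and heat shock (0.819) 1 and 1 each, and Hox 0 (0.56). Notch targets had a median of 0.13 and a mean of -0.25, heat shock -0.55 and 0.17, and ecdysone response -0.64 and -1.11 with a test pointing up. With the floor at the series median phototransduction rose and trachea fell as lists (adjusted p = 0.0113 and 0.0477, and 0.133 and 0.391 with an estimated correlation).

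In this comparison 2085 lm probe sets were higher and 1660 lower in eye discs (1719 and 1329 genes), and on lmC 1863 and 1910. On values as deposited the lm total of 3745 became 6277 and the lmC total of 3773 became 5813. There 22 of 34 named calls upward were lost, such as E(spl)m4-BFM (adjusted p = 0.284), aos (0.228) and rdgC (0.78), with none of 38 downward. Scaling to the 75th percentile moved the share of lm calls higher in eye discs from 55.7% to 44.4% and that of lmC calls from 49.4% to 54.2%.

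Probe sets higher in both eye and leg_ey discs than in control leg discs, which share the 3 leg arrays, numbered 12 on lm, among them those of ey, twit, Ilp8, mtt and Ank2, and 23 on lmC. Independent lists of these sizes would share 1.96 and 2.75, and simulated unchanged groups against shared controls gave at most 7 and 3 in 20 simulations. On lm the count did not exceed the simulations with 75th percentile scaling (6, up to 11 simulated) or on values as deposited (7, up to 17). Lower in both were 2 on lm (0.709 for independent lists, up to 16 simulated) and 9 on lmC (2.07, up to 11), and opposite directions were called for 1 and 5. With the floor at the series median 10 and 19 were lower in both (1.96 and 6.39 for independent lists) and 6 and 17 higher (2.39 and 6.45), with 0 in any simulation. With 75th percentile scaling 7 on lmC were lower in both, where simulations gave up to 6. Over all lm probe sets, which are not independent replicates, the log2 differences correlated at 0.077 with a covariance of 0.397, against 0.664 and 1.65 in the simulations, and on lmC at 0.192 and 0.614 against 0.646 and 1.02. With 3 leg arrays the controls could not be split into parts of 2 or more, so part of any excess may come from the shared controls. The simulated covariance exceeded the observed one in every setting of the overlap, so over all probe sets there was no excess. The simulated counts are therefore not a matched reference for the observed ones. Without leg 49, 16 lm probe sets were higher in both and 0 lower, where simulations gave up to 43 and 41, and on lmC 24 and 2, where they gave up to 21 and 32.

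The 3' to 5' signal of control transcripts, a measure of how complete the labelled target is, differed between groups on lmC arrays. For actin the log2 ratio was 6.17 ± 0.88 in eye discs, 3.06 ± 3.43 in leg discs and 0.85 ± 0.14 in leg_ey discs. For eIF-4a it was 6.85 ± 0.98, 2.95 ± 3.82 and 0.54 ± 0.10, and for GAPDH 5.4 ± 0.47, 2.96 ± 3.72 and 0.58 ± 0.22. The 5' signal was at or below the series median on 1, 3 and 3 of 5 eye arrays and on leg 49, so their ratios, and the eye and leg means, are lower bounds. Eye exceeded leg_ey discs by at least 5.32, 6.31 and 4.82 (exact two-sided permutation p = 0.00794 each, the smallest that 126 splits allow; 0.0238 adjusted over 9 tests), with all 5 eye arrays above all 4 leg_ey arrays. Eye against leg discs gave exact p = 0.107, 0.0714 and 0.179 (smallest possible 0.0179) and leg_ey against leg discs 0.0857, 0.0857 and 0.114 (smallest possible 0.0286). The array leg 49 lay with the eye arrays, at no less than 7.0, 7.35 and 7.25. The arrays leg 50 (0.77, 0.52 and 0.59) and leg 51 (1.40, 0.98 and 1.05) lay with the leg_ey arrays.

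**Figure D4:**
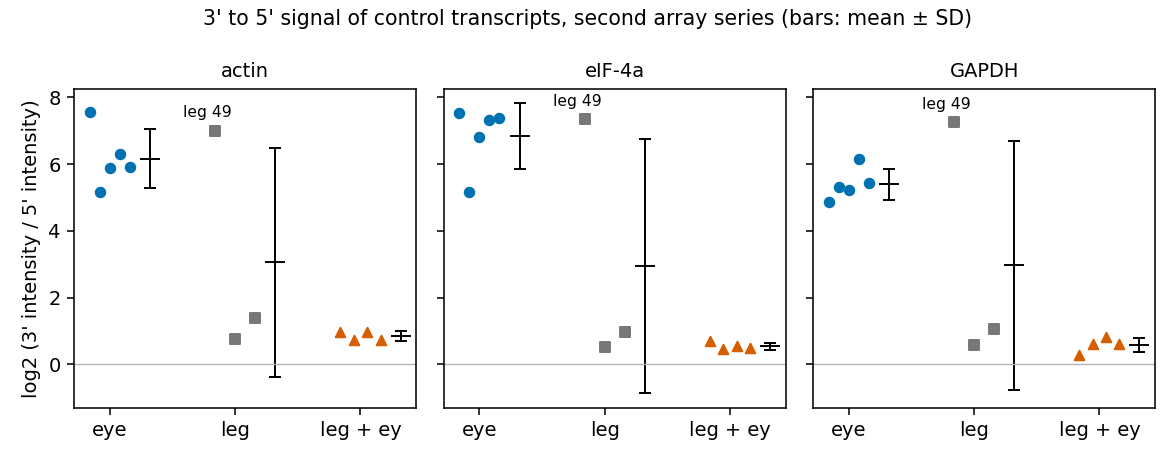
Log2 ratio of 3' to 5' probe set intensity for actin, eIF-4a and GAPDH on each lmC array, with intensities raised to at least the series median of 99.4 before the ratio; points are arrays and bars the mean ± SD, and ratios with the 5' signal raised are lower bounds. All 5 eye arrays and leg 49 lay above all other arrays.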

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

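The test in this part, which asks whether 1 array of a group of 4 or 5 lies far from the rest (Dixon's test), was set before the results were seen. It was run on 298 groups, from 142 named genes, array medians and control ratios, and 28 passed where chance gives about 1 in 20 (14.9). Leg groups of 3 arrays were not tested. All values are normalized intensity on lm arrays, each followed by the range of the other arrays of its group, and none is explained here.

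In eye discs, eye 18 held the highest Sgs3, 6660.3 against 158 to 497, and the highest Lsp2, 8234 against 705 to 2515. It was also highest for dpa (709.9 against -152 to 79.7), trp (639 against -41.6 to 118) and CG12491 (1337 against 482 to 691). The array eye 31 was highest for the retinal genes Optix (1657 against 257 to 527) and eyg (599.6 against -21.6 to 131) and lowest for the cuticle gene Lcp65Ag2 (1270.1 against 3001 to 3553). On eye 29 the caspase gene Drice was 750.4 against -130 to 11.6 and CG1943 was 1767 against -32.7 to 313. On eye 30 the cell death gene rpr was 428 against -460 to -215 and btd was -678 against -262 to -169. On eye 17 CG14154 was 357 against 84.9 to 143.

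In leg_ey discs, leg_ey 54 was highest for Pebp1 (1018 against 742 to 772), the muscle actin gene Act88F (9817 against 6253 to 6808) and SdhB (3998 against 2583 to 2769). It was lowest for verm (8762 against 10815 to 11120), CG1943 (13115 against 18044 to 18433) and CG12491 (-197 against 7.80 to 40.4). The array leg_ey 55 was highest for btd (1363 against 1066 to 1104) and dap (2648 against 1603 to 1723). It was lowest for E(spl)malpha-BFM (3747 against 6788 to 7142), trpl (-42.8 against 84.3 to 98.5) and CG14297 (-62.0 against 1.46 to 4.24). On leg_ey 53 inv was 385 against 159 to 192, brp was -94.9 against 73.9 to 103 and RpS15 was 25459 against 27207 on each other array. The equal RpS15 values are a shared rank, to which quantile normalization gives the same value, so any difference in rank would be flagged there. Ilp8 was lowest on leg_ey 52, at 1297 against 1740 to 1763.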

How the results depend on the processing

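Chosen after seeing the data were the fits without leg 49 or of both leg groups alone with the median floor, those without eye 17 and eye 18, the overlap without leg 49, the retinal determination list without ey, the gene counts from the mean over the probe sets of a gene, and the list settings other than the estimated correlation. Signal over background limits the dim genes: with a floor of 1 on lm many calls rest on values near 0, and with the floor at the series median 9 of the 32 calls between leg_ey and leg discs on lm and 25 of the 46 on lmC were still made. On lm the 10th and 25th percentiles were both negative, so both floors were 1. The floor at the 10th percentile therefore repeated the main fit there and tested nothing. No paired analysis was possible because array numbers are shared between the 2 designs and not between groups, and lmC genes are not named here. As lmC genes are not named, the results over both designs and the fits of both designs with and without a block were not run. The mean over the probe sets of a gene was run on lm, where it gave 1635 genes for eye against leg (1634 with 1 probe set per gene, 1528 of them shared), 21 for leg_ey against leg (25, 21 shared) and 3076 for eye against leg_ey (3048, 2904 shared), and ended 6, 2 and 4 calls of named genes. Where a value moved, the cause was not tested, except that fits of only the groups compared hold fewer arrays.

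On values as deposited, eye against leg gave 4420 calls on lm (1967 with quantile normalization) and 4549 on lmC (2639), eye against leg_ey 6277 (3745) and 5813 (3773), and leg_ey against leg 30 on lmC (46). The share of calls higher in eye discs was then 4.32% and 3.49% on lm and 7.80% and 5.97% on lmC (55.7%, 55.7%, 50.5% and 49.4% with quantile normalization). The median log2 difference of all probe sets tested fell to -1.87 and -2.23 on lm and -1.35 and -1.55 on lmC, and was 0.25 and 0.14 for leg_ey against leg, where the share higher went from 68.75% to 81.5% on lm and from 56.5% to 70% on lmC. With 75th percentile scaling the medians were -0.43 and -0.44 on lm and 0.018 and 0.013 on lmC, the shares 44.5% and 44.4% on lm and 55.7% and 54.2% on lmC, and leg_ey against leg gave 20 calls on lm (32). With only the groups compared in the fit, eye against leg gave 909 and 1503 calls and leg_ey against leg 79 and 161, and 131 on lmC with the median floor too. The median floor alone gave 74 for leg_ey against leg on lmC, and array weights 398 and 960.

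Leaving out 1 array gave 929 (leg 51) to 2047 (leg 49) calls for eye against leg on lm, with 1292 without leg 50, and 1580 (leg 51) to 3048 (eye 31) on lmC. For leg_ey against leg it gave 18 (leg_ey 55) to 139 (leg 50) and 27 (leg_ey 53) to 91 (leg 50), with 21 on lm without leg_ey 54 and 29 on lmC without leg_ey 55. For eye against leg_ey it gave 2589 (leg_ey 52) to 4221 (leg 49) and 2605 (leg_ey 55) to 4187 (eye 31).

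Of 60 named genes called between eye and leg discs, 35 passed in all 12 fits that left out 1 array and 25 in all other planned settings in which they were tested. These were 58 and 40 of 72 for eye against leg_ey, and 6 and 3 of 13 for leg_ey against leg, where ey passed everywhere and Yp1 wherever tested, which leaves out the median floor. Over all settings the values of called genes kept direction and call in 1198 of 1429, 1564 of 1718 and 223 of 319 cases, and lost the call in 227, 150 and 96. These totals overstate stability. They hold 60, 72 and 13 cases from the lowest floor, which repeated the main fit on lm and could not differ. The fold threshold reused the main values and p-values, so it could only end calls of small differences. The mean over the probe sets left the log2 difference of genes with 1 probe set unchanged. On values as deposited, lz (-0.13), rdgC (-0.23) and loco (-0.19) turned negative in eye against leg discs. In eye against leg_ey discs dan (-4.25), danr (-1.60), hth (-1.78), ru (-0.39), E(spl)malpha-BFM (-0.60) and loco (-0.86) did. Hsp83 in eye against leg_ey discs went from -0.97 to 0.026 with 75th percentile scaling. Act57B in eye against leg discs went from 1.04 without leg 50 to -1.29 without leg 49, with the median floor or not, and rpr became 0.070 without leg 49 and with that floor.

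By camera with an estimated correlation 0 lists passed in eye against leg (4 with the preset one), 0 in leg_ey against leg (13) and 0 in eye against leg_ey (3), with 4, 7 and 3 at an unadjusted p under 0.05. On values as deposited 7 passed in eye against leg, and with the median floor 5 in eye against leg_ey. Leaving out 1 array gave 3 (leg 49 or eye 29) to 8 (leg 50) lists in eye against leg, with 7 without eye 18. In leg_ey against leg it gave 6 (leg 49) to 13, with 5 without leg 49 and with ey left out of the retinal determination list, and in eye against leg_ey 3 to 6 (eye 17, leg_ey 54 or leg_ey 55). Probe sets higher in both eye and leg_ey than in leg discs numbered 6 with the median floor, 6 with 75th percentile scaling and 7 as deposited on lm (12), the last 2 below the highest simulated values of 11 and 17, and 15 as deposited on lmC (23). Those lower in both numbered 10 with the median floor and 0 without leg 49 on lm (2), and on lmC 19 with the median floor, 5 as deposited and 2 without leg 49 (9). No simulation with the median floor gave any probe set in both, in either direction.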

Other observations

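The genes in this part outside the rule for named genes, and the 3 patterns weighed, were chosen after their values had been seen. The tests of each pair of glue and fat body genes, those without 2 arrays, those with the leg arrays normalized alone and that of the retinal determination list without ey were chosen after the results had been seen. The other tests of the patterns were set before the values they measure were seen, although the genes leading leg_ey against leg discs without leg 49 had been looked at before the test of ectopic ey was set.

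With the floor at the series median, several genes at background in control leg discs passed in leg_ey discs. The peroxidase gene Pxt was 984 ± 103 against 58.4 ± 21.8 (adjusted p = 0.00236), the receptor kinase-like gene otk 951 ± 113 against -408 ± 527 (0.0167) and the perlecan gene trol 1081 ± 229 against 137 ± 195 (0.0217). A probe set of the polarity gene sdt was 345 ± 43.6 against -169 ± 251 and passed with either floor (0.0219 and 0.0217). It is not the probe set that represents sdt, which was not among the calls with either floor. The probe set W_at, whose name is ambiguous in upper and lower case, was 1181 ± 303 in leg_ey, 246 ± 51.1 in leg and 2094 ± 621 in eye discs (0.0219 and 0.0138).

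Genes lower in leg_ey discs with that floor included the distal leg gene al, 186 ± 82.4 against 1441 ± 172, a log2 difference of -2.79 (adjusted p = 0.000154, and 0.511 with the lower floor). The glutathione transferase gene GstD3 was 94.7 ± 98.4 against 4261 ± 1376 (-4.49, 0.000154, and 0.106), and the larval cuticle gene Lcp3 543 ± 345 against 3379 ± 1614 (0.0219, and 0.79).

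Of the probe sets called between eye and leg_ey discs, 70.9% on lm (2445 of 3448) and 65.3% on lmC (2359 of 3613) differed in the same direction between leg 49 and both other leg arrays, although the leg arrays, which are in neither group, shared the normalization, filter and variance of that fit. With the eye and leg_ey arrays normalized, filtered and fitted alone and the leg arrays normalized alone, the shares were 73.0% (2838 of 3890) and 67.9% (2437 of 3589), while leg 49 was higher for 61.4% and 63.7% of uncalled probe sets. They were 75.9% and 74.1% for those called higher in eye discs, and 69.4% and 61.8% for those called lower. A 3' bias of the eye targets may therefore account for part of these differences on lmC, where leg 49 had 3'-biased control transcripts, and on lm only if its leg 49 carried the same target, since lm holds no such transcripts. Leg 49 also had the lowest deposited median of the leg arrays, 102.45 on lm and 80.1 on lmC. On lmC its 75th percentile lay above that of leg 50. Eye arrays had lower medians than leg_ey arrays, so the shared direction cannot tell 3' bias from low signal. The tissue itself stays open and untested, since eye targets alone had 2 rounds of cDNA synthesis.

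In leg_ey against leg discs 12 gene lists rose by camera with the preset correlation and none with an estimated one. Most had no member past the threshold. Leg 49 may have lowered them in the leg group, as 5 of the 12 lists stayed up without leg array 49. The retinal determination list rose without leg 49 too (adjusted p = 0.000335), but it holds ey itself, which was driven by design. Its other members missed the threshold without leg 49 (0.075, median log2 difference 0.53), so whether ectopic ey raised them stays open. No list passed with an estimated correlation, so both explanations rest on the preset one.

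The salivary glue genes Sgs3 and Sgs7 fell in leg_ey against leg discs. Over the 8 eye and leg arrays, centred by group, the 6 Sgs genes had a median pairwise Spearman correlation of 0.86 (15 pairs, lowest -0.12), and 0.64 with 6 fat body genes (Pearson medians 0.78 and 0.68). By exact two-sided permutation of the arrays within each group (720 orders, smallest p = 0.00139), 0 of 51 pairs passed after adjustment (lowest 0.0708 for Spearman and 0.0773 for Pearson), and 8 of 15 and 10 of 36 had an unadjusted p under 0.05 for Spearman and 7 and 10 for Pearson. Without eye 18 and eye 31, the arrays farthest from the median, the Spearman medians were 0.66 and 0.37 and the Pearson medians 0.60 and 0.40, so the link to fat body rests largely on these arrays and stays open. Salivary gland tissue carried along in some dissections may be a source, though no single pair of its genes passed, while larval age and the leg_ey genotype stay open and untested.

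Other splits of the same arrays were refitted to see whether a chance division gives as many calls. For eye against leg discs 1 of 56 splits, the real one, reached 1967 calls on lm and 2639 on lmC, with at most 414 and 940 in any other, both from splits that set eye 30 and eye 31 with the leg arrays. For leg_ey against leg discs 1 of 35 splits reached 32 and 46, with at most 28 and 8 in any other, both from splits that set leg 50 with leg_ey 52, leg_ey 54 and leg_ey 55. For eye against leg_ey discs 1 of 100 drawn splits reached 3745 and 3773. The highest others there, 1831 and 2756, set eye 31 with all 4 leg_ey arrays and so follow most of the real division. In all 6 cases the real division gave the most calls, so a count as large came from a share of splits under 0.05. The 6 cases were not adjusted for each other, the designs may share RNA, and splits were refitted in the main setting alone. For leg_ey against leg on lm the 32 calls stood little above 28, and 75th percentile scaling gave 20. Chance division is therefore not excluded for that comparison on lm.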
